A study of Mus musculus with 6 samples.

How the data were processed

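Liver sinusoidal endothelial cells, the fenestrated cells that line the small blood vessels of the liver, were isolated from C57BL/6 wild type mice and from mice of the genotype labelled NICeCA. Mice of both genotypes received tamoxifen, which per the labels activated Notch signalling in the NICeCA mice. Total RNA of each isolate was sequenced as paired reads, and 6 libraries were analysed, 3 of each genotype. The labels number the wild type libraries 1, 3 and 4 and the NICeCA libraries 1, 2 and 3. They do not say whether each library came from its own animal, so p-values measure the spread between these libraries, which may be technical in part.

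The authors deposited one table of the whole series with whole-number read counts per gene and an RPKM value beside each count. The counts are raw, not normalised, and the deposited RPKM values equal the count divided by the gene length and by the library's total count, with a largest relative gap of 5.0e-06 over values of 50 counts or more. The RPKM values therefore add no information and served only for this check. The aligner, the counting tool, the genome build and the use of strand are not given in the sources used here. Gene IDs of 35575 rows matched the mouse RefSeq table of assembly GRCm38.p6, and 17318 of those had identical coordinates, so coordinates were those of the deposited table itself. The table held 51165 rows, of which 17861 were at 0 in every library. It held 2 names that occur more than once, and both look like dates made by a spreadsheet; neither was used by name. Many genes of the major histocompatibility complex were listed at 0 in every library, among them H2-K1 and H2-D1, as were Notch4 and Cldn5, so nothing is said here about their level.

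Library totals ran from 26254649 to 30034191 counts. Rows of ribosomal RNA or its repeats took 5.63% of the counts in wild type 1 and between 0.514% and 2.05% in the other libraries. Differential expression was tested on the counts as deposited with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with its minimum count of 10, which left 19795 genes. Libraries were scaled by TMM, dispersions were estimated with estimateDisp, and the groups were compared with glmQLFit and glmQLFTest at default settings. P-values were adjusted by the Benjamini-Hochberg method over all tested genes, with a threshold of 0.05. Standard errors of log2 fold changes are the fold change divided by the square root of its F statistic. Normalised read counts are CPM values from edgeR's cpm function with TMM-scaled library totals, given as mean ± SD over the 3 libraries of a group. The square root of the common dispersion was 0.283 and the prior had 3.07 degrees of freedom.

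The 30 gene lists were fixed before the data were examined and cover Notch signalling, endothelial subtypes, endothelial functions, stress responses and markers of the other cell types a liver isolate could hold. Each was tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the 30 lists. An estimated correlation and fry were run as alternatives. Counts of list members "adjusted over the list alone" use the same quasi-likelihood p-values adjusted within that list.

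The genes named below follow a rule fixed before the data were examined. It took 16 genes of Notch signalling and endothelial identity whatever their result, the genes with the largest change past the threshold with no overlap between groups, at a mean of at least 1 CPM in the higher group and leaving out unnamed gene models, and per list up to 4 members past the threshold or else the member with the smallest p. Further genes were chosen after their values were seen: Gja5, Mecom, Cxcr4, Rspo3, Wnt9b, Dkk3, Cdh13, Jag1, Plxnc1, Tspan7, Clec4g, Stab1, Angpt2, Pdgfb, Ctgf, Bmp4, S100a8, Ltf, Ms4a1, Clec4f, Alb, Mki67, 1110018N20Rik and ENSMUSG00000085151.7, and the remaining list members named as examples. Of the genes this rule picked, 2 are not reported here.

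Both tools were tested on simulated counts of the 19795 genes, drawn from the means, totals and gene-wise edgeR dispersions of these libraries. In these data 100 genes were changed 2-fold and 100 changed 4-fold, and 19413 genes passed the filter again. The quasi-likelihood test recovered 11% of the genes changed 2-fold and 80% of those changed 4-fold, and 7 of its 98 calls were genes that had not been changed. DESeq2 1.42.0 recovered 45% and 93%, and 78 of its 216 calls were genes that had not been changed. The changed genes all had a mean over 1 CPM, and genes were drawn independently of each other, so these shares need not carry over to the real data.

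DESeq2, other filters and scalings, the replicate number as a block, voom with quality weights, a fold threshold and leaving out each library were alternatives fixed before the data were examined. After the first fit had given few genes, the robust prior, bias-corrected deviances, the edgeR exact test, voom without quality weights, a fit without ribosomal RNA-like rows and fits with a Kupffer cell or neutrophil marker score as a covariate were added, and the fit fixed in advance was kept as the main one. No library pair was close enough in its counts to be a repeat deposit of the same library. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.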

Results

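Gene expression was measured by RNA sequencing in liver sinusoidal endothelial cells of 3 wild type and 3 NICeCA libraries, the latter from mice in which tamoxifen activated Notch signalling. The question set by the labels is how Notch activation changes the transcriptome of these cells. Totals ran from 26254649 counts in wild type 3 to 30034191 in wild type 1, so genes at 1 CPM rest on about 26 to 30 counts per library.

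Notch activation was accompanied by higher levels of Notch target and arterial endothelial genes and lower levels of genes that mark sinusoidal and venous endothelium, each tested as a list. None of these 4 lists passed with an estimated correlation between genes (adjusted p from 0.176 to 0.341). Neutrophil, B cell and T cell lists were also higher with the preset correlation and not with an estimated one, and T cell markers did not separate the genotypes. The Notch target and arterial lists share Hey1, Hey2, Dll4, Efnb2, Gja4, Gja5, Jag1 and Unc5b, so they are in part 1 result. Without genes held by another list, the Notch target and venous lists were too small to test, while the arterial and sinusoidal lists still passed. Hey1, a transcriptional repressor induced directly by Notch, rose from 5.85 ± 0.588 CPM to 32.3 ± 7.41 CPM (SD, n = 3 per group), which is 5.51-fold. Esm1, a proteoglycan secreted by endothelial tip cells, rose 10.1-fold from 39.0 ± 11.4 CPM to 394 ± 89.1 CPM. Wnt2, a Wnt ligand that sinusoidal and central-vein endothelium supplies to hepatocytes, fell from 280 ± 58.6 CPM to 32.3 ± 11.6 CPM, a log2 fold change of -3.12 ± 0.29 (SE). In each of these genes all 3 NICeCA libraries lay on one side of the 3 wild type libraries.

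Of 19795 genes tested, 9 passed the threshold with edgeR's quasi-likelihood test, 5 higher and 4 lower in NICeCA. The other genes that rose were Slc45a4, which encodes a proton-coupled sugar transporter, by 3.41 ± 0.21 on the log2 scale (SE), the smooth muscle myosin heavy chain Myh11 by 1.59 ± 0.15 and the cyclin-dependent kinase Cdk6 by 1.37 ± 0.12. Adjusted p by edgeR was 0.0159 for Slc45a4 and 0.0367 for Hey1, Esm1, Wnt2, Myh11 and Cdk6. Among the genes that fell were also 1110018N20Rik, with a log2 fold change of -2.29 ± 0.23, and ENSMUSG00000085151.7, with -2.38 ± 0.23. These overlap each other, so their reads cannot be told apart there. At an unadjusted p under 0.05, 3266 genes differed where chance gives 990, and 23.4% of tested genes had no overlap between the groups where chance gives 10%. Pearson correlations of log2 CPM ran from 0.962 to 0.968 within wild type, 0.969 to 0.980 within NICeCA and 0.924 to 0.974 between genotypes. Wild type 4 and wild type 1 correlated with NICeCA 1 (0.974 and 0.972) above every pair within wild type. The first principal component, with 48.5% of the variance, was negative in each wild type library and positive in each NICeCA library. DESeq2 called 1107 genes, 733 higher and 374 lower, including all 9. A gene is said to pass only where edgeR's quasi-likelihood test called it, and DESeq2's calls are named as such. Without wild type 1, wild type 3, wild type 4 or NICeCA 3 the quasi-likelihood test called 0 genes, at unadjusted counts between 2078 and 3695, while DESeq2 called 389 to 1454 over the 6 sets of libraries. Without NICeCA 2 it called 1, Slc45a4, and without NICeCA 1 it called 14.

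**Figure D1:**
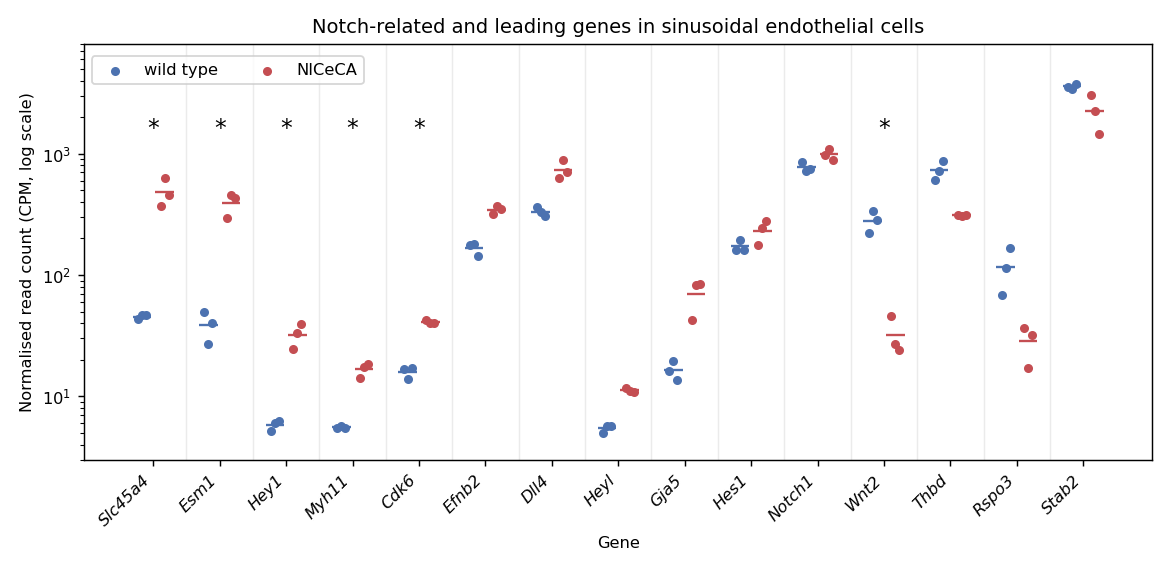
Normalised read counts (CPM, log scale) of 15 genes in each of the 6 libraries, wild type in blue and NICeCA in red, with the group mean as a line and an asterisk over genes past the edgeR threshold. Hey1 lay at 5.85 CPM on average in wild type and 32.3 CPM in NICeCA, and Wnt2 at 280 CPM and 32.3 CPM; the groups of Hes1 overlap.

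Notch1 itself was counted in every library, with 24104, 18878 and 20600 reads in wild type 1, 3 and 4 and 29497, 32492 and 26904 reads in NICeCA 1, 2 and 3. Its log2 fold change was 0.36 ± 0.15 with no overlap between the groups, and neither edgeR (adjusted p = 0.294) nor DESeq2 (0.153) called it. Among 19 tested Notch target genes, 14 had a positive and 5 a negative log2 fold change, with a median of 0.99, and the list was higher as a group (camera adjusted p = 1.10e-10). With an estimated correlation its adjusted p was 0.176. Hey1 alone passed over all genes with edgeR, DESeq2 called 9 members higher and 2 lower, and 10 members were higher and 2 lower when edgeR's p was adjusted over the list alone. Heyl was at 1.04 ± 0.15 on the log2 scale without passing with edgeR (adjusted p = 0.0941; 2.52e-06 with DESeq2), and Nrarp, a feedback inhibitor of Notch, stood at 1.46 ± 0.39 (adjusted p = 0.194 with edgeR and 0.00507 with DESeq2). Hes1 at 0.43 ± 0.18 and Hey2 at 0.34 ± 0.36 overlapped between groups and were called by neither tool. The list of Notch receptors, ligands and pathway components did not pass as a group (camera adjusted p = 0.951). Its members went both ways, with Dll4 at 1.14 ± 0.16, Notch3 at 1.35 ± 0.38 and Jag1 at 1.02 ± 0.23 against Dll1 at -0.64 ± 0.17 and the glycosyltransferase Lfng at -0.82 ± 0.24. None of these 5 passed over all genes with edgeR, while DESeq2 called each. Adjusted over the list alone, 4 of its 21 tested members were higher and 3 lower. Its median was negative and its mean positive.

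Arterial endothelial genes rose as a group (camera adjusted p = 8.91e-15), with 19 of 24 log2 fold changes positive and a median of 0.89. The adjusted p was 0.176 with an estimated correlation, and 13 members were higher and 2 lower when adjusted over the list alone. Efnb2, the arterial ephrin ligand, had a log2 fold change of 1.05 ± 0.13 (adjusted p = 0.0706, edgeR), the arterial connexin Gja5 2.10 ± 0.29 (0.0893), the transcription factor Mecom 1.05 ± 0.13 (0.0734), the lymphangiogenic growth factor Vegfc 1.57 ± 0.24 (0.0962) and the chemokine receptor Cxcr4 2.65 ± 0.42 (0.0970). None of these passed over all genes with edgeR, while DESeq2 called each, and the groups did not overlap in any. Over the list DESeq2 called 13 higher and 2 lower. The connexin Gja4 and the chemokine Cxcl12, also in this list, had negative values of -0.82 ± 0.22 and -0.80 ± 0.18. Leukocytes also express Cxcr4, and neutrophil markers were higher in the same libraries, at a median log2 fold change of 2.41.

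The 27 sinusoidal identity genes were lower as a group (camera adjusted p = 4.32e-12), and all 27 had a negative log2 fold change, with a median of -0.48. Without NICeCA 3 the median was -0.32 with 23 of 27 negative, and without NICeCA 1 it was -0.70. With an estimated correlation the adjusted p was 0.341. Wnt2 passed over all genes with edgeR, Wnt2, Plxnc1 and Tspan7 passed when adjusted over the list alone, and DESeq2 called 7 members, all lower. The scavenger receptor genes Stab2 and Stab1 had log2 fold changes of -0.68 ± 0.28 and -0.53 ± 0.25, Clec4g -0.72 ± 0.24, and the hyaluronan receptor Lyve1 -0.25 ± 0.23. None of these 4 passed with edgeR, and DESeq2 called Clec4g (adjusted p = 0.0399). Lyve1 was at -0.076 without wild type 3 and -0.46 without wild type 4. Without NICeCA 3, Stab2 and Stab1 were at -0.44 and -0.33, and with a neutrophil marker score as a covariate in DESeq2 at -0.42 ± 0.39 and -0.28 ± 0.33. With a Kupffer marker score they were at -0.82 ± 0.25 and -0.65 ± 0.22, and DESeq2 called both (0.0221 and 0.0471). The median deviation of the list was between 0.24 and 0.28 in the wild type libraries and 0.041, -0.21 and -0.63 in NICeCA 1, 2 and 3. NICeCA 3 was also the library with the lowest pan-endothelial level, at -0.33 against 0.065 to 0.11 elsewhere, and the highest neutrophil marker level, at 2.97. The scavenging and endocytosis genes were lower as a group (camera adjusted p = 0.000238, 19 of 23 negative), with an adjusted p of 0.491 with an estimated correlation. This list shares Stab1, Stab2, Mrc1, Fcgr2b, Lyve1, Ehd3, Cd36 and Ctsl with the sinusoidal list, so it is not a separate result for them. Colec12, a scavenger collectin, was the member with the smallest p, at -1.12 ± 0.19, and did not pass with edgeR, while DESeq2 called it (0.000191) and in all 3 lower and 1 higher member. Pan-endothelial genes were lower by less, with a median of -0.21 and 14 of 18 negative (camera adjusted p = 0.0211; adjusted p = 0.525 with an estimated correlation). Egfl7 had the smallest p there, at -0.50 ± 0.14, and did not pass with edgeR, and was the 1 member DESeq2 called (0.0321). Without NICeCA 3 that list's adjusted p was 0.242, and without wild type 1 it was 0.0710.

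**Figure D2:**
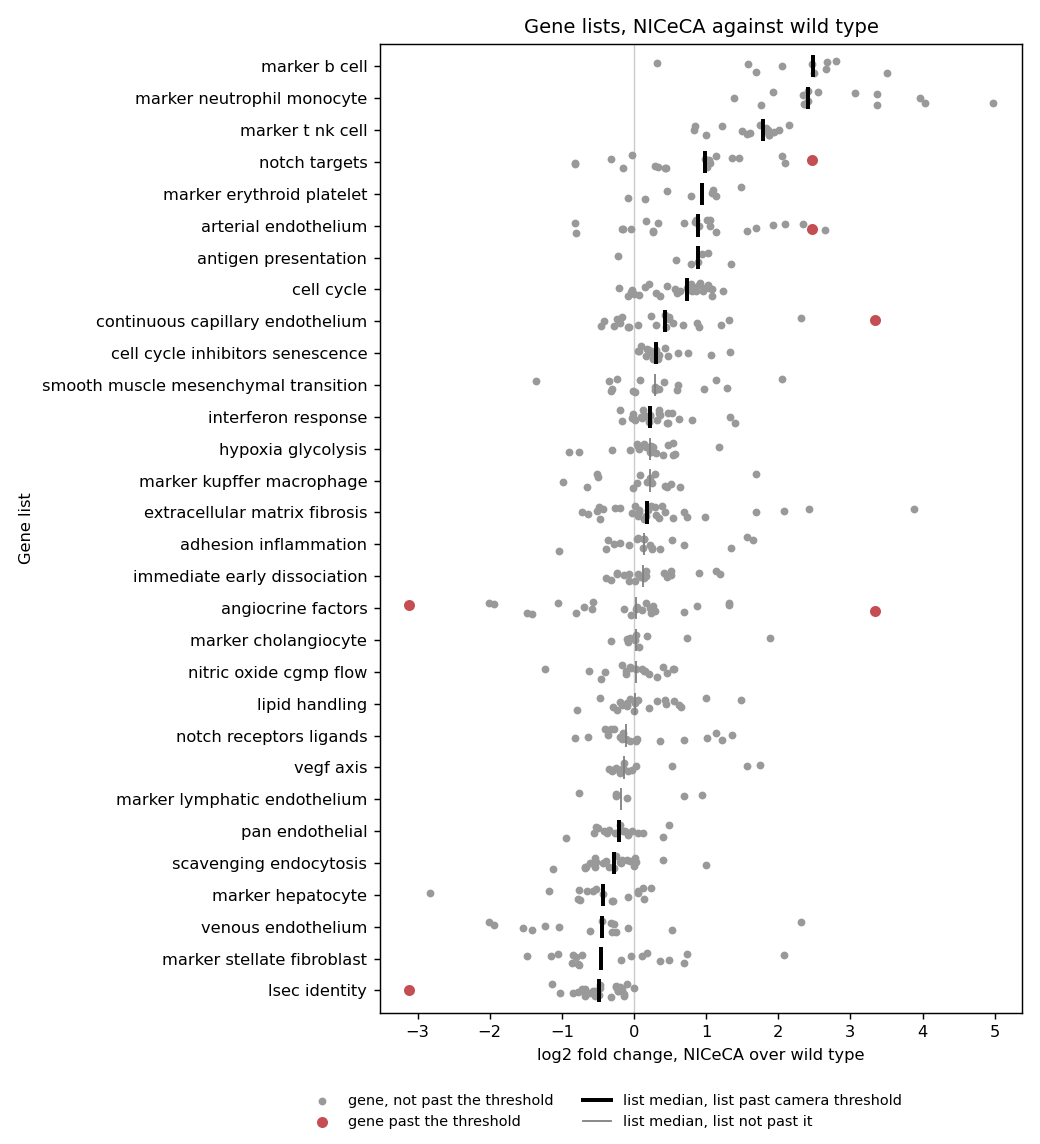
Log2 fold change, NICeCA over wild type, of each tested gene in the 30 lists, with red points for genes past the edgeR threshold and a line at the list median, thick and black where the list passed camera at the preset correlation. All 27 sinusoidal identity genes (lsec identity) lay below 0, and the medians of the B cell and neutrophil markers lay at 2.48 and 2.41.

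Venous endothelial genes were lower as a group (camera adjusted p = 4.28e-08), with 13 of 15 log2 fold changes negative, and the adjusted p was 0.176 with an estimated correlation. Adjusted over the list alone, 7 were lower and 1 higher. The Wnt potentiator Rspo3 had a log2 fold change of -2.01 ± 0.39, Wnt9b -1.41 ± 0.38, Dkk3 -1.94 ± 0.36, Cdh13 -1.54 ± 0.23 and thrombomodulin (Thbd) -1.23 ± 0.16, and each had no overlap between groups. None passed over all genes with edgeR, Thbd coming nearest (adjusted p = 0.0748), while DESeq2 called these 5. The 2 positive members were Aplnr, the apelin receptor, at 2.31 ± 0.82 and Ackr1 at 0.53 ± 0.38, which neither tool called. Secreted angiocrine factors did not pass as a group (camera adjusted p = 0.0541), the median being 0.033 while the mean was -0.20. They passed as lower in 7 of 20 other settings, among them no filter (0.0288), DESeq2 size factors (0.0474), median log2 ratio scaling (0.0481), without wild type 1 (0.00213) and without NICeCA 3 (0.0320). Among them Wnt2 fell and Esm1 rose. Hgf stood at -1.05 ± 0.15, Bmp4 at -1.48 ± 0.32, Angpt2 at 0.88 ± 0.16, Pdgfb at 1.31 ± 0.27 and Ctgf at 1.32 ± 0.32, without passing over all genes with edgeR, while DESeq2 called each. Hgf is also in the stellate cell and fibroblast list, so its value cannot be assigned to endothelial cells. Continuous-capillary genes rose as a group (camera adjusted p = 0.000359; adjusted p = 0.341 with an estimated correlation), with 15 of 23 positive and Esm1 the member that passed with edgeR. DESeq2 called 3 members higher, Esm1, Angpt2 and Pdgfb. The 8 negative members included Cav1 at -0.46 ± 0.13 and Plvap at -0.41 ± 0.21, which neither tool called. With fry the adjusted p of the list was 0.0825. Cd34, often used as a marker of capillarisation, was at 0.67 ± 0.25 and Col4a1 at 0.43 ± 0.22, with overlapping groups and no call by either tool.

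Cell cycle genes were higher as a group (camera adjusted p = 4.55e-06, 26 of 30 positive, median 0.73), with an adjusted p of 0.504 with an estimated correlation. Mki67 was at 1.03 ± 0.36 and Cdk1 at 1.08 ± 0.30, and none of the 30 passed with edgeR over all genes or when adjusted over the list alone. DESeq2 called Cdk1 (0.0218). The median deviation of the list was 0.31 in wild type 3, close to 0.35 to 0.43 in the NICeCA libraries, and -0.50 and -1.03 in wild type 1 and 4. Cell cycle inhibitors and senescence genes were also higher (camera adjusted p = 0.00361, 17 of 17 positive, median 0.30), with an adjusted p of 0.450 with an estimated correlation. Gadd45a led them at 1.33 ± 0.39 without passing with edgeR, and was 1 of 2 members DESeq2 called (0.0154). It was at 0.79 without NICeCA 3 and at 0.19 ± 0.37 with the neutrophil score as a covariate in DESeq2. Without wild type 4 the adjusted p of the list was 0.0918. The groups overlapped in the median deviation of the list, at 0.027 in wild type 1 and 0.0040 in NICeCA 1. Extracellular matrix genes passed as higher (camera adjusted p = 0.0195, 21 of 30 positive; adjusted p = 0.341 with an estimated correlation). Col1a1, a fibrillar collagen gene, was at 2.08 ± 0.33 (adjusted p = 0.0970 with edgeR and 2.86e-07 with DESeq2), and the list did not pass without wild type 1 (0.120), wild type 4 (0.0918) or NICeCA 1 (0.0814). The groups also overlapped in its median deviation, at 0.028 in wild type 3 and 0.0042 in NICeCA 3. The contractile and mesenchymal transition list did not pass camera (adjusted p = 0.147), and 12 of 18 members were positive. Acta2, smooth muscle actin, was at 2.05 ± 0.32 (adjusted p = 0.0962, edgeR), and the transcription factor Twist1 at -1.36 ± 0.27, and DESeq2 called both. Acta2, which is also in the Notch target list, averaged 2.33 ± 0.206 CPM in wild type and 9.66 ± 3.51 CPM in NICeCA. Whether Acta2 and Myh11 transcripts came from endothelial cells or from smooth muscle cells in the isolate was not tested. Fry, which asks whether the genes of a list move on balance in one direction, gave the contractile and mesenchymal transition list an adjusted p of 0.0429, the value it also gave the arterial, Notch target and B cell lists.

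Interferon response genes were higher as a group (camera adjusted p = 0.000873, 21 of 25 positive, median 0.23), with an adjusted p of 0.616 with an estimated correlation. Their median deviation did not separate the genotypes, being 0.14, 0.042 and -0.60 in wild type 1, 3 and 4. In NICeCA 1, 2 and 3 it was 0.23, 0.30 and -0.076. The antiviral gene Oas2 was at 1.40 ± 0.27 without passing with edgeR, while DESeq2 called it (0.000133), and without wild type 4 the list's adjusted p was 0.467. Antigen presentation was represented by 7 tested genes, 6 of them positive (camera adjusted p = 0.00829; adjusted p = 0.341 with an estimated correlation), with the costimulatory gene Cd80 at 0.88 ± 0.23, which DESeq2 called and edgeR did not. With the neutrophil score as a covariate in DESeq2, Cd80 was at 0.45 ± 0.40 and not called. With the Kupffer score it was at 0.92 ± 0.29 and called (0.0347). Without NICeCA 1 the list's adjusted p was 0.101. Of the 18 genes in that list, H2-K1 and H2-D1 were listed at 0 in every library.

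Markers of other cell types differed between the libraries as well. B cell markers were higher in NICeCA (camera adjusted p = 6.14e-14, 10 of 10 positive, median 2.48), with an adjusted p of 0.176 with an estimated correlation. Their levels were low. Pax5 averaged 0.374 ± 0.235 CPM in wild type and 2.63 ± 0.240 CPM in NICeCA, and Ms4a1 0.157 ± 0.159 CPM and 1.83 ± 0.485 CPM, and neither passed over all genes with edgeR. DESeq2 called both and 8 of the 10 members. Neutrophil and monocyte markers were higher as a group (camera adjusted p = 4.99e-11, 15 of 15 positive), with an adjusted p of 0.392 with an estimated correlation. Elane, a neutrophil elastase, was at 4.98 ± 0.81 without passing with edgeR, while DESeq2 called it (7.63e-10). S100a8, an abundant neutrophil transcript, was at 305 ± 322 CPM in wild type and 1621 ± 1523 CPM in NICeCA, and the groups overlapped. T and NK cell markers were higher as a group (camera adjusted p = 8.53e-08, 16 of 16 positive, adjusted p = 0.425 with an estimated correlation), with Cd4 at 2.15 ± 0.54, called by DESeq2 and not by edgeR. Their median deviation did not separate the genotypes, being 0.69 in wild type 1, -1.88 and -2.26 in wild type 3 and 4, and -0.20, 1.56 and 1.74 in NICeCA 1, 2 and 3. Erythroid and platelet markers passed as higher (camera adjusted p = 0.0359, adjusted p = 0.504 with an estimated correlation). The member with the smallest p was Hbb-bt at 1.14 ± 0.53, whose reads can be shared with near-identical globin genes. That list did not pass without wild type 1 (0.120), wild type 3 (0.211), NICeCA 1 (0.143) or NICeCA 3 (0.0632). Its highest median deviation was that of wild type 4, at 0.98, against 0.75, -0.0043 and 0.85 in NICeCA 1, 2 and 3.

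Hepatocyte markers were lower as a group (camera adjusted p = 0.0195, 12 of 17 negative; adjusted p = 0.707 with an estimated correlation). Their median deviation did not separate the genotypes, being -0.46, 0.32 and 1.04 in wild type 1, 3 and 4. In NICeCA 1, 2 and 3 it was 0.17, -0.79 and 0.20. Cyp2e1, which pericentral hepatocytes express most, was at -2.83 ± 0.52 and albumin (Alb) at 0.14 ± 0.30, and neither passed with edgeR, while DESeq2 called Cyp2e1 (2.22e-06). Without wild type 4 or NICeCA 2 the adjusted p was 0.583 and 0.403. Stellate cell and fibroblast markers were lower (camera adjusted p = 0.0398, 11 of 18 negative; adjusted p = 0.504 with an estimated correlation), although Col1a1 was positive. They did not pass without wild type 3 (0.0961), wild type 4 (0.191), NICeCA 2 (0.156) or NICeCA 3 (0.0577). The groups overlapped in their median deviation, which was -0.21 in wild type 1 and -0.052 in NICeCA 1. Kupffer cell markers did not pass between the genotypes (camera adjusted p = 0.486), and libraries of the same genotype differed in them. The Kupffer marker Clec4f stood at 418, 368 and 323 CPM in wild type 4, NICeCA 1 and NICeCA 2 and at 22.0, 36.9 and 48.7 CPM in wild type 1, wild type 3 and NICeCA 3. Slc40a1, which had the smallest p of that list, was at -0.51 ± 0.26.

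**Figure D3:**
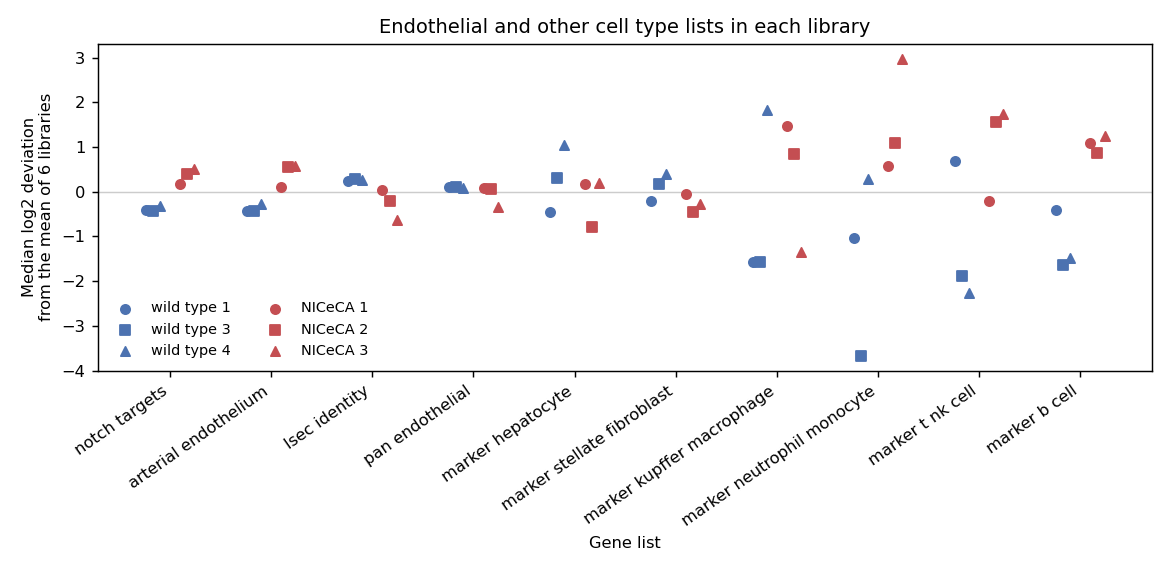
Median log2 deviation from the mean of the 6 libraries for 10 lists, one point per library, wild type in blue and NICeCA in red, with the library given by the marker shape. Notch target and arterial medians lay below 0 in each wild type library and above 0 in each NICeCA library, while the Kupffer median was at 1.82 in wild type 4 and -1.34 in NICeCA 3.

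The other lists did not pass. These were nitric oxide and flow genes (camera adjusted p = 0.613), with Nos3 at -0.41 ± 0.15, the VEGF axis (0.936), with Kdr at -0.14 ± 0.23, lipid handling (0.586), with Fabp5 at -0.79 ± 0.22, and hypoxia and glycolysis (0.294), with Ndrg1 at -0.77 ± 0.15. Adhesion and inflammation genes (0.317) included Icam2 at -0.39 ± 0.13, and immediate early genes (0.294), which respond to cell dissociation, included Nr4a1 at 1.20 ± 0.25. Cholangiocyte markers (0.672) did not pass either, and lymphatic endothelial markers (0.703) had Reln, which is also in the stellate cell list, at -0.77 ± 0.24. Of the genes named for these lists edgeR called none, and DESeq2 called Fabp5, Ndrg1 and Nr4a1. The smallest p belonged to Thbd in the nitric oxide list and to Vegfc in the VEGF list, both given above and called by DESeq2. Median, mean or test differed in sign for the nitric oxide, lymphatic and VEGF lists.

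In all, 18 of 30 lists passed with the preset correlation, 12 higher and 6 lower, and 0 passed with an estimated correlation, where 4 had an unadjusted p under 0.05. Splits of the libraries that mix the genotypes passed between 5 and 17 lists with the preset correlation. The quasi-likelihood test recovered 11% of simulated 2-fold and 80% of simulated 4-fold changes, and DESeq2's larger count includes an unknown share of false calls, 78 of 216 in the simulation. The simulation changed 100 genes by each fold, where 3266 real genes had an unadjusted p under 0.05. Its shares therefore need not hold for these data.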

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

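The robust prior, bias-corrected deviances, the exact test, voom without quality weights, the fit without ribosomal RNA-like rows, both covariate fits and every alternative to the DESeq2 count were chosen after seeing the data. The count of 9 genes stayed at 9 with DESeq2 size factors, median log2 ratio scaling, a 2-fold threshold or no ribosomal RNA-like rows, and was 10 with the robust prior or bias-corrected deviances and 11 at a mean of at least 5 CPM, the same 9 genes among them each time. It became 111 with no filter, 1107 with DESeq2, 818 with the edgeR exact test, 27 with voom and quality weights and 5 with voom without weights. It was 0 with the Kupffer score (3275 genes at an unadjusted p under 0.05) or the neutrophil score (936) as a covariate in edgeR, where DESeq2 called 1175 and 139 genes. Leaving out 1 library gave 0 to 14 genes. It was 0 without wild type 1, 3 or 4 or NICeCA 3, and 14 without NICeCA 1, which leaves as many libraries. The DESeq2 count was 691 at 2-fold or more and ran from 389 to 1454 over the libraries left out, with 604 without wild type 3, 528 without NICeCA 2 and 389 without NICeCA 3. The count of 18 lists became 0 with an estimated correlation and 4 with fry, 3 of them among the 18, and was between 13 and 19 in every other setting. The cause was not tested for the filter, the tools, the covariates or the libraries left out.

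The groups share replicate numbers 1 and 3 only. Deviations of same-numbered libraries correlated at -0.21 and -0.25, so the numbers were not taken as pairs, and with the replicate block edgeR called 0 genes (1596 at an unadjusted p under 0.05), DESeq2 382, and camera 14 lists.

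Directions held for 61 of the 66 named genes in every setting, and those that turned did so without passing. With the neutrophil score as a covariate, log2 fold changes were 0.29 for Lyve1, 0.029 for Kdr, -0.69 for S100a8, -0.16 for Clec4f and -0.49 for Alb. S100a8 is part of that score, so its value there is not informative. Leaving out 1 library gave -0.24 to 0.029 for Kdr, positive without NICeCA 3, and -0.084 to 0.43 for Alb, negative without wild type 3 or NICeCA 3.

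Lists whose direction turned had these camera adjusted p-values. At a mean of at least 5 CPM the Notch receptor list had 0.777 and the nitric oxide list 0.952. With the replicate block the VEGF list had 0.633, interferon 0.682, hepatocyte 0.173 and lymphatic 0.856. The Notch receptor list had 0.945 with DESeq2 and 0.784 with fry. With voom and quality weights the nitric oxide and VEGF lists had 0.950 and cholangiocyte markers 0.761, and VEGF had 0.782 without weights. Without genes held by another list, nitric oxide had 0.684 and VEGF 0.889. With the Kupffer score as a covariate, lipid handling had 0.847 and Kupffer markers 0.275. With the neutrophil score, the Notch receptor list had 0.306, adhesion 0.111, immediate early 0.0755, hypoxia 0.262, Kupffer 0.509, neutrophil 0.266, erythroid 0.510 and cholangiocyte 0.00141, the last being the 1 that passed in the new direction. The neutrophil list under the neutrophil score and the Kupffer list under the Kupffer score were adjusted for their own members, so those turns are not informative. Over the libraries left out the ranges were 0.596 to 0.968 for Notch receptors, 5.59e-08 (without wild type 4) to 0.835 for Kupffer, 0.0439 (without wild type 4) to 0.891 for cholangiocyte, 0.0174 (without wild type 1) to 0.806 for adhesion, 0.465 to 0.831 for VEGF and 0.0708 to 0.780 for immediate early genes. The cause was not tested. Of the other list results, 479 kept direction and side of the threshold, 67 lost the threshold and 14 gained it. For named genes these numbers were 1141, 70 and 94.

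A pseudocount, quantile normalisation, limma without trend and a comparison of the authors' own were not run, since the table holds raw counts and no comparison. At totals of 26254649 to 30034191 counts, how far depth limits genes near 1 CPM was not tested.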

Other observations

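Of the tests below, those of the gene count over other splits, the neutrophil and Kupffer markers, the endothelial share, the scaffolds, the covariates and the reduced zonation lists were chosen only after the result was seen, and those of the full zonation lists and of the list count over other splits before.

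Wnt2 was lower in NICeCA, and Dll4 and Efnb2 had positive log2 fold changes of 1.14 and 1.05, called by DESeq2 and not by edgeR, which led to the hypothesis that Notch activation may shift endothelial zonation away from the central vein and towards the portal side. A list of central-vein endothelial genes and one of portal endothelial genes were drawn up from genes whose values had not yet been seen. All 9 tested central-vein genes had a negative log2 fold change, with a median of -1.41 (camera p = 6.73e-17 with the preset correlation, p = 0.0243 with an estimated correlation, unadjusted). Kit was at -2.02 ± 0.37 (SE), Rspo3 at -2.01 ± 0.39, Ptgs1 at -1.24 ± 0.24, Fabp4 at -0.47 ± 0.24 and Ccdc3 at -0.022 ± 0.36, which is close to 0. Of 7 portal genes 6 were positive, with a median of 0.81 (camera p = 8.21e-05, p = 0.0453 with an estimated correlation, unadjusted), among them Gpr126 at 1.48 ± 0.26, Galnt15 at 1.14 ± 0.25, Ntn4 at 0.81 ± 0.26 and Ltbp4 at 0.87 ± 0.27, with Adam23 at -0.54 ± 0.21. None of these genes passed over all genes with edgeR, while DESeq2 called Kit, Rspo3, Ptgs1, Gpr126, Galnt15 and Ltbp4 among them. Both predictions held, but 5 of the 9 central-vein genes are also in the venous list and Ltbp4 is in the arterial list, so the central-vein test largely repeats the venous result. Without these members, 4 central-vein genes had a median of -0.85 (camera p = 3.52e-05, p = 0.0433 with an estimated correlation) and 6 portal genes one of 0.65 (p = 0.000653, p = 0.0650 with an estimated correlation). The 4 are Kit, Ptgs1, Fabp4 and Ccdc3, fewer than the 5 required of a list elsewhere, and the fall rests mainly on Kit and Ptgs1. A change in which endothelial cells the isolation recovered was not tested and stays open beside one within the cells.

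Neutrophil and monocyte markers differed between libraries widely, and co-isolated neutrophils or their RNA are a candidate source. If 1 source supplied these transcripts, they should rise and fall together, and 13 of 14 members (92.9%) correlated with S100a8 over the 6 libraries at r over 0.8. For Kupffer markers 13 of 16 (81.2%) did so with Clec4f, and these were high in wild type 4, NICeCA 1 and NICeCA 2, which cuts across the genotypes. S100a8 ran from 32.5 CPM in wild type 3 to 3369 CPM in NICeCA 3, and Ltf averaged 84.3 and 871 CPM in the groups. The neutrophil list shares 0 genes with the other lists and the Kupffer list 0. No sort is named in the labels. Whether the higher leukocyte signal of NICeCA came with the isolation or was present in those livers cannot be read from these libraries. The neutrophil score was higher in every NICeCA library (0.72, 0.98 and 2.92) than in any wild type library (-1.03, -3.60 and 0.019). It is therefore tied to genotype. A lost call or smaller fold under it cannot assign a change to leukocytes rather than to genotype, and a kept call does not clear one. With the neutrophil score as a covariate, DESeq2 called 139 genes in place of 1107 and edgeR 0. Hey1 went from 2.47 ± 0.24 to 2.22 ± 0.36 (log2 fold change by DESeq2 ± SE), Wnt2 from -3.11 ± 0.28 to -2.66 ± 0.38 and Dll4 from 1.15 ± 0.18 to 1.19 ± 0.28, and DESeq2 still called these 3. The Kupffer score left 46 of 47 calls of named genes in place. With the neutrophil score, of 47 named genes that DESeq2 called, 25 kept the call, 22 lost it and 0 changed direction. Of the 22, the SE was larger in 21 and the fold smaller in 18. The call ended for Heyl (1.05 ± 0.18 to 1.09 ± 0.31, adjusted p = 0.0526) and Nrarp (1.46 ± 0.37 to 1.66 ± 0.58, 0.248), where the SE grew and the fold did not shrink. It also ended for Jag1 (1.02 ± 0.25 to 0.90 ± 0.39, 0.631) and Gja4 (-0.81 ± 0.23 to -0.56 ± 0.34), where the SE grew and the fold shrank, as for Acta2 (2.06 ± 0.35 to 1.84 ± 0.57, 0.110), Dkk3 (-1.93 ± 0.35 to -1.90 ± 0.55, 0.0668), Hgf (-1.05 ± 0.18 to -0.94 ± 0.28, 0.0898), Plxnc1 (-1.13 ± 0.25 to -0.99 ± 0.39, 0.434) and Pdgfb (1.32 ± 0.29 to 0.95 ± 0.42, 0.660). Among the others that lost it, Cxcr4 went from 2.65 ± 0.40 to 1.67 ± 0.50 (0.0830) and Gadd45a from 1.33 ± 0.38 to 0.19 ± 0.37. Whether these 2 follow the leukocytes or the genotype cannot be told apart by this fit.

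The sinusoidal identity list was lower in NICeCA, and a lower share of endothelial cells in those libraries could account for it. Such a share should lower all endothelial genes alike, provided the cells that take their place express none of these genes. Whether leukocytes express some of the pan-endothelial genes was not tested. The pan-endothelial median lay 0.27 above the sinusoidal one on the log2 scale, with a bootstrap SE over genes of 0.13, so the gap passes 2 SE only narrowly, and genes are not independent. Over the libraries left out the gap ran from 0.18 without NICeCA 3 to 0.44 without NICeCA 1. With all libraries the test argues against dilution as the whole cause by a thin margin only, and only if the diluting cells lack pan-endothelial transcripts. A gap of 0.18, as without NICeCA 3, would not pass 2 of that SE. A contribution of dilution therefore stays open, and not only in NICeCA 3, where pan-endothelial genes were lowest. A change in which endothelial cells the isolation recovered also stays open, beside an effect of Notch on the sinusoidal programme.

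Genes of the major histocompatibility complex were listed at 0 in all libraries, although B2m had 41490 to 56062 counts. Among genes named H2, 28 of 40 were at 0. A candidate explanation is that reads matching both a chromosome and an alternate scaffold were not counted. Of protein-coding genes that the table places on scaffolds, 344 of 618 (55.7%) were at 0 in every library against 4281 of 21357 on chromosomes, and 42.7% of the chromosomal neighbours of scaffold-listed genes against 18.2% of other genes. The share on scaffolds lies between the one that such a loss was taken to need and the chromosomal one, so whether scaffold matches account for the zeros cannot be told apart from other losses in counting. No biological explanation was tested.

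The 6 libraries can be split into groups of 3 in 10 ways, too few for a share under 0.05. The real split gave 9 genes and the highest of the others 10, so 2 of 10 splits gave at least as many. That other split set wild type 1, wild type 3 and NICeCA 3 against the rest, which are the libraries low in Kupffer markers, and it had 371 genes at an unadjusted p under 0.05 where the real split had 3266. For gene lists the real split gave 18 and the others between 5 and 17, so 1 of the 10, the real one, reached that number. Groupings that mix the genotypes thus also passed many lists at the preset correlation, and a list past it is weak evidence of a genotype difference.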
